A study of Mus musculus with 4 samples.

How the data were processed

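Gene expression was measured in single cells of the mouse thoracic aorta, the first part of the body's main artery, with 10x Genomics droplet capture. In this method each transcript is tagged at its 3′ end and counted once by a unique molecular identifier (UMI). Per the labels' protocols, 3 mice were pooled for each library, fat around the vessel was removed, the tissue was digested with enzymes, and cells were stained with the dye DAPI and sorted for viability before capture. The design had 4 libraries, 1 for each combination of genotype (wild type, WT, or whole-body knockout of Sting, KO) and treatment (saline or angiotensin II, AngII). AngII is a peptide hormone that constricts arteries and raises blood pressure. Saline mice ate a normal diet, whereas AngII mice were infused for 7 days and were fed a high fat diet for 5 weeks, so the infusion and the diet cannot be separated in any comparison. Each library was assigned to its group from its title and characteristics.

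The authors deposited whole-number UMI counts per gene and cell barcode, with no normalization; the kind of value was read from the files and Cell Ranger and the genome build mm10 are named in the submitters' processing notes. The Cell Ranger version, the gene annotation and any filter on cells or genes are not given in the sources used here. All 4 libraries listed the same 17524 gene symbols in the same order. The largest number of detected genes in a cell was between 4911 and 4998 and the highest mitochondrial share was between 22.8% and 24.8% in the 4 libraries, which shows that cells had been filtered before deposit.

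The deposited matrices held 9261 cells (WT saline), 8495 (WT AngII), 12053 (KO saline) and 8507 (KO AngII), with 60064040, 90581104, 76841968 and 94698720 UMIs. Cells with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. Scrublet, a caller of droplets with 2 cells as implemented in scanpy, marked 1, 1, 0 and 1 cells, although 7.41%, 6.80%, 9.64% and 6.81% would be expected at 0.8% per 1000 cells. The caller therefore did not work here, and doublets remain in the data. An alternative removed the cells with the highest doublet scores up to those shares (686, 577, 1162 and 579 cells). The kept cells numbered 9241, 8474, 12024 and 8495.

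Cells of all libraries were clustered together without batch correction (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), and every cluster of at least 100 cells was divided once more at resolution 0.5. Clusters were named from 17 marker lists fixed before the data were examined. A name needed a marker score of at least 0.6, at least 3 markers each detected in 10% of the cells, and no larger number of another class's markers among the 10 genes leading the cluster over cells of other classes. Clusters with a score of at least 0.5 for another of the 4 main classes (smooth muscle, fibroblast, endothelial and mononuclear phagocyte) were called mixed and kept out. These naming rules were written after the data had been seen. Names ending in -like mean only that the cluster carried those markers. A class was compared only with at least 50 cells in both libraries. Endothelial-like cells (75, 16, 48 and 17) reached this only in WT saline and were not compared.

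For each class and library the counts were summed over cells and divided by the class total to give CPM, the counts per 1000000 UMIs of the class. The log2 ratio of 2 libraries is given with its 95% exact conditional interval, which treats UMIs as independent counts. CPM values have exact Poisson intervals and cell shares have exact binomial (Clopper-Pearson) intervals. All of these cover counting error only, not differences between mice or between library preparations. With 1 library per group no test was made, no p-value is given, and no difference has a replicate check. Genes were eligible with at least 100 UMIs in the library with the higher CPM and, to limit free RNA from other cells, a CPM there of at least 0.1 of the gene's highest CPM in any class of that library. Where a class has fewer UMIs in 1 library, a gene needs a higher CPM there to reach 100 UMIs. Splits into higher and lower genes therefore lean towards the library with more UMIs of the class. A gene at 0 in 1 library was set to a floor of 3 UMIs and its ratio is written as a bound. List medians hold such genes at that bound.

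Genes were described through 26 fixed lists of pathway and cell state genes. Median log2 ratios of the lists cover members with at least 50 UMIs over both libraries that also passed the free RNA limit. Each median is given with the number of members at least 1.5-fold apart. Its percentile is among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile describes these libraries and is not a test. Named genes followed a fixed rule: per comparison and class, the 3 higher and 3 lower genes whose counting interval ended farthest from 0, leaving out mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed gene models and markers of other classes, plus up to 4 members with the largest ratio of each list described and Tmem173. Some genes that met this rule are not reported here. The lists, markers, comparisons, naming of genes and 14 of the 20 alternative settings were chosen before the data were examined. The other 6 alternatives were added after seeing the data, as was the choice of the 21 list medians that open the comparisons.

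Genes with close copies, such as Ifit3 and Ifit3b, Hspa1a and Hspa1b, Pbp2 or the H2 genes, can share reads that counting may split or discard, so their values are uncertain. Positions are taken from the GENCODE annotation of GRCm38, the assembly also called mm10, matched by symbol. Computation used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9. TMM and median-of-ratios factors, used only as alternative scalings, came from edgeR 4.0.16 in R 4.3.3.

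The counting and ratio steps were tested on simulated counts with 200 genes set apart, drawn from the real class means and totals of each comparison. In the smooth muscle comparison of WT AngII with WT saline (10668 genes), all genes set 2.83-fold or 4-fold apart came out at least 2-fold apart with the right sign, and no unaltered gene did. In phagocytes of KO AngII and KO saline (2342 genes) these shares were 96.3% at 2.83-fold, 100% at 4-fold and 2.38% of unaltered genes, and in phagocytes of KO saline and WT saline (1069 genes) they were 100%, 100% and 0%. Because depth per cell differed between treatments, an alternative thinned each cell to 3000 UMIs. This left out 221 smooth muscle-like, 386 fibroblast-like and 26 phagocyte-like cells of WT saline and 1329, 69 and 3 of KO saline, but none of these classes in the AngII libraries.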

Results

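Single-cell transcriptomes of the thoracic aorta were compared to ask what the DNA-sensing adaptor STING, a protein that triggers interferon production, contributes in the aorta with and without AngII. Each of the 4 groups was 1 library from 3 pooled mice. Total UMIs were 60064040 in WT saline, 90581104 in WT AngII, 76841968 in KO saline and 94698720 in KO AngII, and median UMIs per cell were 5888, 9938, 6071 and 9294. AngII libraries were thus deeper per cell than saline libraries. In all comparisons AngII stands for the infusion together with the high fat diet.

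The targeted gene was examined first. Tmem173, which encodes STING (chromosome 18, 35733679 to 35740554, minus strand, GRCm38), gave 105 UMIs in WT saline, 635 in WT AngII, 102 in KO saline and 578 in KO AngII. These correspond to 1.75 CPM (95% Poisson interval 1.43 to 2.12), 7.02 (6.49 to 7.59), 1.33 (1.08 to 1.61) and 6.11 (5.62 to 6.63). Among fibroblast-like cells the levels were 5.95, 15.7, 12.1 and 12.2 CPM, and in phagocyte-like cells 27.7, 44.7, 25.2 and 37.1 CPM. The gene was therefore not depleted in the libraries labelled KO. A 3′ tag that lies outside the altered part of a gene checks nothing, and the altered part is not given in the sources used here, so the counts neither bear out nor rule out the genotype labels. "KO" below means the library labelled Sting-KO.

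Smooth muscle-like cells were the largest class, followed by fibroblast-like and mononuclear phagocyte-like cells (macrophages and monocytes). Smooth muscle-like cells formed 78.6% of WT saline (exact interval 77.7 to 79.4), 66.7% of WT AngII (65.7 to 67.7), 82.1% of KO saline (81.4 to 82.7) and 64.3% of KO AngII (63.3 to 65.4). Fibroblast-like cells made up 11.6% (10.9 to 12.2), 19.9% (19.1 to 20.8), 2.96% (2.67 to 3.28) and 23.0% (22.1 to 23.9). Phagocyte-like cells made up 2.71% (2.38 to 3.06), 7.45% (6.90 to 8.03), 0.466% (0.352 to 0.604) and 5.71% (5.23 to 6.22). Both of these classes had larger shares in the AngII libraries of either genotype. Mixed clusters held 3.32%, 3.72%, 12.5% and 4.12% of cells and unnamed clusters 3.04%, 2.02%, 1.61% and 2.63%. The shares follow dissociation and a DAPI viability sort, and the saline and AngII libraries differed in depth. Giving mixed clusters to their first class brought the KO saline shares to 6.76% for fibroblast-like and 0.690% for phagocyte-like cells.

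**Figure D1:**
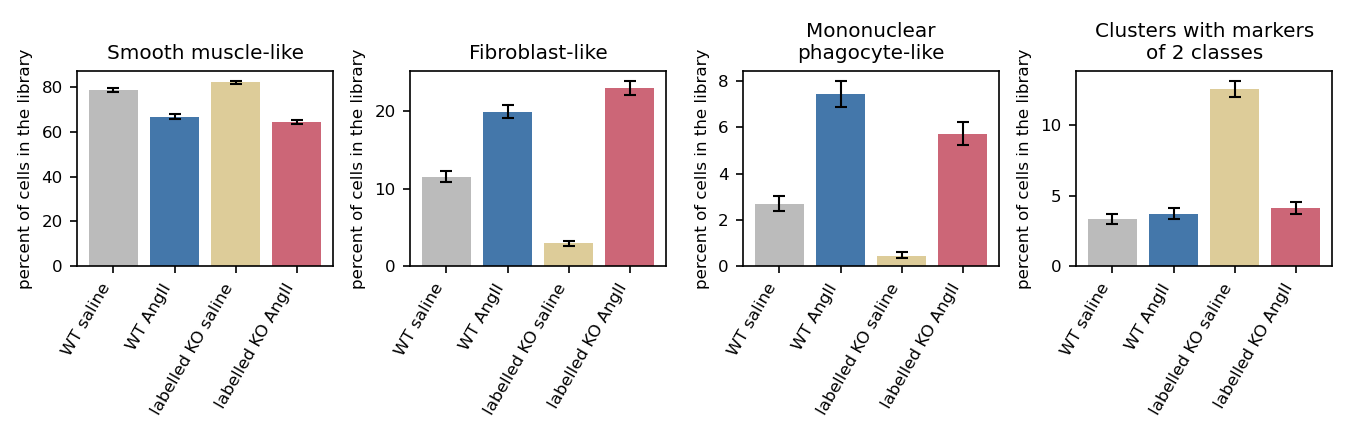
Share of cells (percent of the library, axis from 0) in each class and in clusters with markers of 2 classes, per library, with exact binomial 95% intervals that cover counting error only. Fibroblast-like cells were 2.96% of KO saline and between 11.6% and 23.0% of the other libraries, and mixed clusters held 12.5% of KO saline.

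Smooth muscle-like and fibroblast-like cells came largely from different clusters in different libraries. Smooth muscle-like cells lay mostly in clusters 0 and 1 in WT saline (50.0% and 45.9%), clusters 12 and 15 in WT AngII (49.1% and 40.8%), clusters 11, 13 and 9 in KO saline (39.1%, 28.0% and 27.9%) and clusters 15, 10 and 13 in KO AngII (32.6%, 20.1% and 19.9%). Cluster 9 came to 98.6% from KO saline and its cells were shallow, with a median of 3228 UMIs, so 27.9% of the KO saline class is a low-UMI set. Fibroblast-like cells lay in clusters 8 and 7 in WT saline (61.0% and 38.4%) and KO saline (58.7% and 39.6%), in clusters 4 and 7 in WT AngII (72.2% and 22.3%) and in clusters 4 and 5 in KO AngII (80.8% and 9.31%). The AngII libraries filled different parts of these clusters: the part led by Saa3 and Mmp3 held 384 cells of WT AngII and 76 of KO AngII, that led by Cxcl1, Fst and Ccl7 held 63 and 659, that led by Crabp2, Timp1 and Prg4 held 71 and 364, and a part of cluster 7 led by Isg15, Ifit3 and Ifit1 held 48 and 2. All phagocyte-like cells of each library lay in cluster 3, but in different parts of it. The part led by Ccl24, Lyve1 and Retnla held 199 of 250 cells of WT saline and 32 of 56 of KO saline but 28 of 631 of WT AngII and 10 of 485 of KO AngII. The part led by Cd74, H2-Ab1 and H2-Aa held 4, 7, 238 and 125 cells of these libraries, and the part led by Ccl8, Ccl12 and Folr2, with Ifi27l2a also among its leading genes, held 28, 2, 103 and 2. Free RNA was measurable but low: Acta2, a smooth muscle transcript, reached in phagocyte-like cells 3.03%, 1.92%, 4.05% and 2.81% of its smooth muscle CPM in WT saline, WT AngII, KO saline and KO AngII. Lyz2, a phagocyte transcript, reached in smooth muscle-like cells 0.0769%, 0.165%, 0.0526% and 0.109% of its phagocyte CPM.

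AngII was first compared with saline in WT smooth muscle-like cells. Genes of collagen and fibrosis were higher with AngII: all 11 measured members were at least 1.5-fold higher, with a median log2 ratio of 1.78 (percentile 100). Spp1 (osteopontin) had a log2 ratio of 6.27, the protease inhibitor Timp1 3.31, the matrix glycoprotein Tnc 2.14 and Col1a1 1.99. Genes of the unfolded protein response, which handles misfolded proteins in the endoplasmic reticulum, were also higher (median 1.07, percentile 100, 10 of 14 members higher and none lower), among them Sdf2l1 at 3.50, Creld2 at 1.76 and Manf at 1.67. The contractile apparatus was lower (median −0.50, percentile 0.04), with 7 of 14 members at least 1.5-fold lower and none higher. Its lowest members were Synpo2 at −1.05, Lmod1 at −0.91, Des at −0.80 and the smooth muscle myosin Myh11 at −0.75.

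Of 10668 eligible genes in these cells, 443 were at least 2-fold higher and 468 at least 2-fold lower with AngII. TMM and median-of-ratios scaling each moved all ratios by 0.11 and gave 541 higher and 364 lower, or 543 and 362. By the fixed rule the genes farthest apart upward were Lcn2, which encodes the iron-trafficking protein lipocalin 2, with 611 UMIs against 1 (log2 ratio 8.98, interval 6.49 to 14.28), Spp1 (234 against 3.03 CPM, 6.27, interval 6.04 to 6.51) and the endothelial proteoglycan gene Esm1 (19.9 against 0.178 CPM, 6.80, interval 5.87 to 7.93). Downward they were Cyp2b10 (0.0653 against 2.81 CPM, −5.43, interval −7.33 to −4.04), the glucocorticoid-responsive gene Fkbp5 (3.25 against 53.3 CPM, −4.04, interval −4.25 to −3.83) and Slc10a6 (0.147 against 3.17 CPM, −4.43, interval −5.59 to −3.47). Elastic fibre genes had a median of 0.65, with 5 of 10 members higher, led by elastin (Eln, 1.51) and the crosslinking enzyme Lox (1.17), and 1 lower. Genes of modulated smooth muscle had a median of 2.46, with 6 of 7 members higher, including Tnfrsf11b (3.61) and the adhesion molecule Vcam1 (2.46). Cholesterol synthesis genes had a median of 0.82 (10 of 14 higher, 1 lower), with Cyp51 at 1.52.

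WT fibroblast-like cells showed a larger fibrosis difference. All 14 collagen and fibrosis genes were at least 1.5-fold higher with AngII (median log2 ratio 2.73, percentile 100), led by Cthrc1, a secreted protein of injured arteries and fibrotic tissue, at 6.20, periostin (Postn) at 4.50, Col8a1 at 3.67 and Tnc at 3.24. Inflammatory cytokine genes had a median of 2.32, with 7 of 9 members higher: the monocyte chemokines Ccl2 at 3.19 and Ccl7 at 2.79 and the neutrophil chemokine Cxcl1 at 2.76 were among these, while the eosinophil chemokine Ccl11 stood at −2.59. Of 23 interferon-stimulated genes 11 were higher and 1 lower (median 0.54, percentile 99.99), with Cxcl10 at 3.70, Oas1a at 3.03, Ifi44 at 2.12 and Isg15 at 1.90. Unfolded protein response genes had a median of 1.52 (9 of 15 higher, 1 lower) and lipid handling genes one of −1.10 (4 of 6 lower, 1 higher).

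In WT fibroblast-like cells 622 of 6905 eligible genes were at least 2-fold higher and 401 at least 2-fold lower. The class held 17524447 UMIs in WT AngII and 4202689 in WT saline, so the UMI minimum favours higher genes in this split. The alternative scalings moved all ratios by 0.15 and gave 789 higher and 304 lower, or 787 and 304. Saa3, an acute phase apolipoprotein, was at least 248-fold higher (177 CPM against 0 UMIs) and Ddah1, which degrades methylarginines, at least 199-fold higher (142 CPM against 0 UMIs), while Cthrc1 stood at 1685 against 22.8 CPM (interval of the log2 ratio 5.92 to 6.51). Mrgprg was at least 428-fold lower (0 UMIs against 73.3 CPM). Inmt (9.59 against 408 CPM, −5.41, interval −5.65 to −5.18) and Angptl7 (30.8 against 1165.0 CPM, −5.24, interval −5.37 to −5.11) were the other genes named as lower.

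Phagocyte-like cells of WT AngII differed in composition of monocyte and macrophage genes. Recruited monocyte genes were higher than in WT saline in all 6 measured members (median log2 ratio 3.04, percentile 100), 2 of them from 0 UMIs. Plac8 was at least 25.5-fold higher, the chemokine receptor Ccr2 had a ratio of 3.76, Fn1 3.46 and Ly6c2 2.62. Resident macrophage genes were lower (median −1.62, percentile 0, 7 of 8 members lower and none higher), with the hyaluronan receptor Lyve1 at −3.13, Cd163 at −2.33, Timd4 at −1.97 and F13a1 at −1.78. Antigen presentation genes of MHC class II were higher in 6 of 6 members (median 1.19), whereas immediate early and heat shock genes were lower in 12 of 18 members and higher in 1 (median −0.84).

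Of 3243 genes eligible in these phagocytes 342 were at least 2-fold higher and 105 lower with AngII. The UMI minimum favours higher genes here too, since the class held 5230999 UMIs in WT AngII and 1191440 in WT saline. Spp1 reached 1323 against 5.04 CPM (log2 ratio 8.04, interval 6.91 to 9.48) and the matrix protein gene Thbs1 was at least 83.1-fold higher (209 CPM against 0 UMIs). The chemokine gene Ccl24 (92.0 against 1124 CPM, −3.61, interval −3.76 to −3.46), Lyve1 (243 against 2131 CPM, interval −3.23 to −3.03) and Sult1a1 (35.7 against 289 CPM, −3.01, interval −3.28 to −2.75) were lower. The 2 saline libraries had few phagocyte-like cells (250 and 56, against 631 and 485 with AngII), which limits every phagocyte value, and the ratios combine shifts between parts of the phagocyte cluster with differences inside them. With mixed clusters given to their first class the recruited monocyte median was 2.33.

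The same treatment comparison was then made between the libraries labelled KO. Smooth muscle-like cells of KO AngII again had higher collagen and fibrosis genes (median log2 ratio 1.53, percentile 100, 10 of 11 members higher and none lower), with Spp1 at 8.75, Timp1 at 3.82, Tnc at 2.17 and fibronectin (Fn1) at 1.84. The contractile apparatus had a median of −0.31 (percentile 0.38), with 4 of 14 members at least 1.5-fold lower (Synpo2 −1.003, Myh11 −0.85, Lmod1 −0.81 and Mylk −0.60) and none higher. Cholesterol synthesis genes were higher in 10 of 14 members (median 1.32), with Fdps at 2.22 and Cyp51 at 2.12. Unfolded protein response genes had a median of 0.43 with 5 of 15 members higher and none lower.

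In KO smooth muscle-like cells 399 of 10906 eligible genes were at least 2-fold higher and 558 lower. TMM scaling moved all ratios by 0.17 (501 higher, 352 lower) and median-of-ratios scaling by 0.19 (518 and 339), so the majority of genes 2-fold apart turned from lower to higher, and the contractile median came to −0.13 and −0.12. Spp1 stood at 305 against 0.706 CPM (interval of the log2 ratio 8.34 to 9.20), Pbp2 was at least 111-fold higher (4.99 CPM against 0 UMIs) and the metalloprotease gene Adam12 reached 15.4 against 0.105 CPM (7.19, interval 6.15 to 8.51). Rab17 (1.13 against 9.46 CPM, −3.06, interval −3.46 to −2.69), Psd (1.36 against 10.6 CPM, −2.96, interval −3.32 to −2.62) and the glypican gene Gpc3 (2.49 against 16.5 CPM, −2.73, interval −2.99 to −2.48) were lower.

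KO fibroblast-like cells combined higher fibrosis genes with lower interferon-stimulated genes in AngII. Collagen and fibrosis genes had a median of 2.59 (percentile 100, 13 of 14 higher and none lower), with Cthrc1 at 6.22, Tnc at 4.39, Spp1 at 3.92 and Timp1 at 3.46. Interferon-stimulated genes had a median of −2.08 (percentile 0), with 15 of 18 members lower and none at least 1.5-fold higher. Usp18 stood at −3.16, Ifit3 at −2.90, the RNA sensor gene Ifih1 at −2.68 and the transcription factor gene Irf7 at −2.46. MHC class I presentation genes were lower in all 8 measured members (median −1.24). Inflammatory cytokine genes had a median of 2.67, with 7 of 9 members higher and 2 lower.

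Here 729 of 5350 eligible genes were at least 2-fold higher and 348 lower, with 1148 and 211 under TMM scaling (all ratios moved by 0.32) and 1116 and 216 under median-of-ratios scaling (0.30). Class totals of 25823103 UMIs in KO AngII and 1980452 in KO saline make the UMI minimum favour higher genes in this split. Ddah1 had 3671 UMIs against 1 (log2 ratio 8.14, interval 5.66 to 13.44), Cthrc1 1245 against 16.7 CPM (interval 5.73 to 6.76), and Cxcl14, a chemokine gene, was at least 37.0-fold higher (56.1 CPM against 0 UMIs). Inmt (3.72 against 158 CPM, −5.41, interval −5.76 to −5.08), Cytl1 (29.4 against 847 CPM, −4.85, interval −4.98 to −4.73) and Dact2 (2.01 against 64.6 CPM, −5.00, interval −5.50 to −4.53) were lower. The saline side rested on 356 cells, and with a minimum of 300 UMIs the interferon-stimulated median was −1.14.

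KO phagocyte-like cells had lower MHC class II genes in AngII than in saline. The median log2 ratio was −1.55 (percentile 0) and all 6 measured members were lower, among them the invariant chain gene Cd74 at −1.69, H2-DMa at −1.61, H2-Eb1 at −1.60 and H2-Ab1 at −1.51. Resident macrophage genes were lower in 6 of 8 members (median −0.76), and recruited monocyte genes higher in 4 of 5 and lower in 1 (median 1.16). Of 2342 eligible genes 246 were at least 2-fold higher and 45 lower, and the alternative scalings moved all ratios by 0.15 and 0.12. With 3828694 UMIs of the class in KO AngII and 357367 in KO saline, the UMI minimum strongly favours higher genes in this split. Thbs1 was at least 28.6-fold higher (240 CPM against 0 UMIs), Spp1 had 2153 UMIs against 3 (log2 ratio 6.07, interval 4.52 to 8.34) and the fatty acid binding protein gene Fabp5 395 against 16.8 CPM (4.56, interval 3.43 to 6.00). Retnla (205 against 5415 CPM, −4.72, interval −4.84 to −4.60), the lectin gene Mgl2 (69.7 against 736 CPM, −3.40, interval −3.65 to −3.15) and Ccl24 (115 against 778 CPM, −2.76, interval −2.98 to −2.54) were lower. KO saline contributed 56 cells to this comparison. In these cells all 6 MHC class II members stood above WT saline (H2-Ab1 3204 against 771 CPM). The lower class II ratios thus start from a high saline value. The part of cluster 3 led by Cd74, H2-Ab1 and H2-Aa held a larger share of the phagocyte-like cells in KO AngII than in KO saline.

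The AngII ratios of both genotypes, which share no library, were set side by side. In smooth muscle-like cells 219 genes were at least 2-fold higher with AngII in both genotypes, against 12.4 for independent lists among 10516 genes, 194 were lower in both (19.2 for independent lists) and 4 went opposite ways. In fibroblast-like cells these numbers were 337 (63.8), 131 (12.9) and 5 among 4574 genes, and in phagocyte-like cells 76 (17.9), 21 (1.18) and 7 among 1835. Across genes, which are not independent replicates, the ratios of WT and KO had Pearson correlations of 0.75, 0.77 and 0.62 in smooth muscle-like, fibroblast-like and phagocyte-like cells, and Spearman correlations of 0.67, 0.70 and 0.45.

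The AngII ratios of the genotypes also differed. In fibroblast-like cells the KO ratio minus the WT ratio had a median of −2.39 for interferon-stimulated genes, and all 18 measured members were lower by at least 1.5-fold; the medians were 0.33 in WT and −2.08 in KO for the same genes. For MHC class II in phagocyte-like cells the median difference was −2.70 (1.19 in WT and −1.55 in KO), with 6 of 6 members lower. In the same cells recruited monocyte genes had a median difference of −2.55 (3.46 and 1.16, 4 of 5 members lower) and resident macrophage genes one of 1.08 (−1.62 and −0.76, 5 of 8 higher). Unfolded protein response genes in smooth muscle-like cells had a median difference of −0.57 (1.07 and 0.42), with 7 of 14 members lower and 1 higher. These genes, and MHC class II genes in phagocyte-like cells, were already higher in KO saline than in WT saline. Both of these differences therefore rest at least in part on the saline libraries. The number of genes with ratios at least 2-fold apart between genotypes was 403 in smooth muscle-like, 429 in fibroblast-like and 173 in phagocyte-like cells. These differences combine 4 libraries and were not tested.

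**Figure D2:**
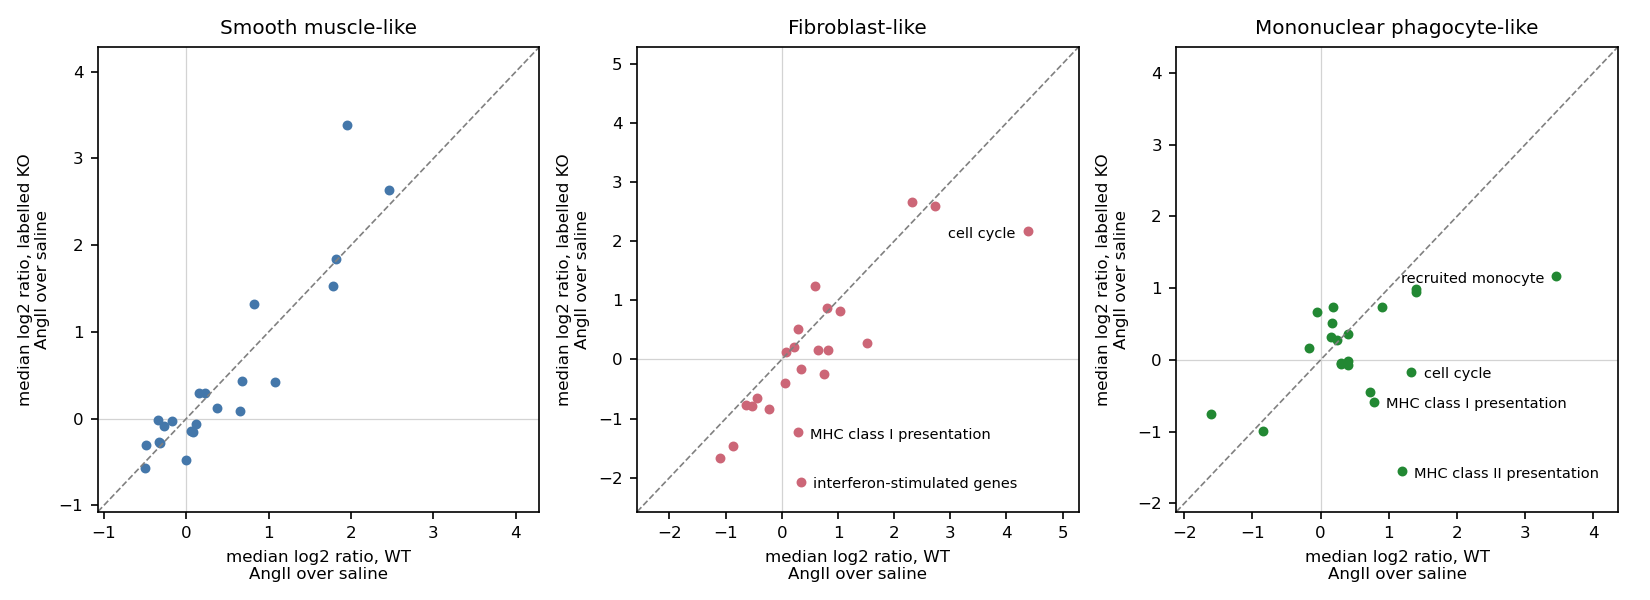
Median log2 ratio of AngII over saline per gene list in the library labelled KO (vertical axis) against WT (horizontal axis), 1 point per list and 1 panel per class, with equality on the dashed line. Labels mark the lists whose members differed most, such as interferon-stimulated genes in fibroblast-like cells (0.33 in WT, −2.08 in KO).

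KO AngII was compared directly with WT AngII, to ask how the genotypes differed under AngII. In fibroblast-like cells all 23 measured interferon-stimulated genes were at least 1.5-fold lower in KO AngII, with a median log2 ratio of −3.06 (percentile 0). Ifi44 stood at −5.23, Ifit3b at −4.50, Irf7 at −4.35 and Ifit3 at −4.21, and the smallest difference was that of Cxcl10 at −0.85. Phagocyte-like cells showed the same direction: 21 of 23 interferon-stimulated genes were lower and none higher (median −1.82, percentile 0), with Irf7 at −3.71, Ifit3b at −3.01, Ifit2 at −2.87 and Ifit3 at −2.61. Ratios of both classes combine shifts between parts of clusters with differences inside them. Cholesterol synthesis genes were higher in KO AngII in smooth muscle-like cells (median 0.99, percentile 100, 11 of 14 higher, none lower; Cyp51 1.44, Fdps 1.41, Insig1 1.29, Sqle 1.14) and in fibroblast-like cells (median 1.44, percentile 100, 13 of 14 higher, none lower; Sqle 2.56, Fdps 2.37, Cyp51 2.04). Immediate early and heat shock genes, which tissue dissociation is known to induce, were also higher in smooth muscle-like cells of KO AngII (median 0.75, 11 of 18 higher, none lower) but had medians of −0.16 in fibroblast-like and 0.07 in phagocyte-like cells, so handling is not separated from the smooth muscle result.

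**Figure D3:**
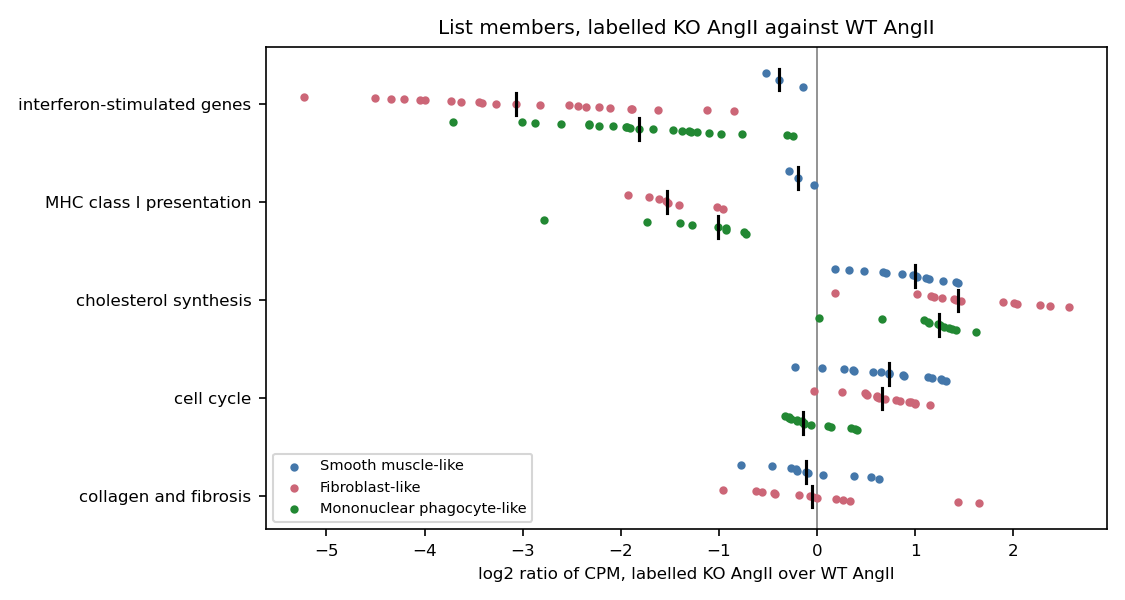
Log2 ratio of CPM in KO AngII over WT AngII (horizontal axis) for members of 5 gene lists (vertical axis), 1 point per gene coloured by class, with a black bar at each median. Interferon-stimulated genes lie left of 0 in fibroblast-like (median −3.06) and phagocyte-like cells (median −1.82), and cholesterol synthesis genes lie right of 0 in all 3 classes.

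MHC class I presentation genes were lower in KO AngII fibroblast-like cells in all 8 measured members (median −1.53), including the immunoproteasome subunit gene Psmb9 at −1.93, H2-D1 at −1.71 and B2m at −1.61. In phagocyte-like cells 9 of 9 class I genes (median −1.01) and 6 of 6 class II genes (median −0.85) were lower, and 11 of 12 cholesterol synthesis genes were higher (median 1.24). Elastic fibre genes of fibroblast-like cells had a median of −0.53 (6 of 13 lower, 1 higher), with Fbln5 at −1.22. Cytokine genes of these cells went both ways (median 0.77, 5 of 9 higher and 3 lower), with the neutrophil chemokine Cxcl5 at 1.77 and Ccl7 at 1.23 but Saa3 at −1.83. Collagen and fibrosis genes had medians of −0.11 in smooth muscle-like cells (1 of 11 members higher and 1 lower) and −0.06 in fibroblast-like cells (2 of 14 higher and 2 lower). Interferon-stimulated genes of smooth muscle-like cells could be measured for 3 members only, after the UMI minimum and the free RNA limit. A cluster led by Ifit1, Ifit3 and Isg15 with a smooth muscle score of 0.774 was left unnamed and is outside the class (18 cells of WT saline, 26 of WT AngII, 2 of KO saline and 4 of KO AngII).

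Smooth muscle-like cells of KO AngII and WT AngII had 107 genes at least 2-fold higher and 53 lower in KO among 10645. Fibroblast-like cells had 167 higher and 357 lower among 9383, with 220 and 271 under TMM scaling or 226 and 270 under median-of-ratios scaling (all ratios moved by 0.11), and phagocyte-like cells had 20 higher and 113 lower among 4596. In smooth muscle-like cells the homeobox genes Hoxc10 (chromosome 15, 102966796 to 102971893, plus strand), at least 179-fold higher (8.76 CPM against 0 UMIs), Hoxa10 (8.23 against 0.0816 CPM, log2 ratio 6.66, interval 5.42 to 8.29) and Hoxd8 (169 UMIs against 3, 5.93, interval 4.36 to 8.22) led the higher side. Lcn2 (0.478 against 9.97 CPM, −4.38, interval −5.00 to −3.83), Mir143hg (23.0 against 85.1 CPM, −1.89, interval −1.98 to −1.80) and Smim5 (17.8 against 53.7 CPM, −1.60, interval −1.70 to −1.49) led the lower side.

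In fibroblast-like cells Cd24a (28.2 against 2.74 CPM, log2 ratio 3.36, interval 2.94 to 3.81), the water channel gene Aqp2 (88.4 against 11.98 CPM, 2.88, interval 2.68 to 3.09) and Cxcl14 (56.1 against 7.48 CPM, 2.91, interval 2.65 to 3.18) were higher in KO AngII. Otor had 1 UMI against 393 (−9.18, interval −14.49 to −6.69), the class I gene H2-Q6 1 against 134 (−7.63, interval −12.94 to −5.12) and Car3 2 against 136 (−6.65, interval −9.71 to −4.77). In phagocyte-like cells Ctla2a (1.71, interval 1.53 to 1.90), Fabp5 (1.501, interval 1.37 to 1.63) and Cd209d (1.55, interval 1.23 to 1.86) were higher in KO AngII, and the chemokine gene Ccl5 (6.27 against 109 CPM, −4.12, interval −4.78 to −3.54), Irf7 (11.2 against 147 CPM, interval −4.19 to −3.27) and AW112010 (18.0 against 195 CPM, −3.44, interval −3.81 to −3.08) were lower. Hoxc10 and Hoxa10 were also among the 10 leading genes of cluster 10 over all other cells, after Rgs5, P2rx1 and Des. This cluster came almost wholly from KO AngII, so Hoxc10 and Hoxa10 mark both a class difference and a cluster. Clusters led by Hoxc10 below means those with Hoxc10 among these 10 genes.

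The saline libraries were compared to ask how the genotypes differed without AngII. Interferon-stimulated genes were lower in KO saline in fibroblast-like cells (median log2 ratio −0.68, percentile 0, 11 of 20 members lower), with Ifit3 at −1.59, Ifit3b at −1.41, Ifit1 at −1.27 and Usp18 at −1.24, although Cxcl10 was higher at 2.31. In phagocyte-like cells 8 of 13 members were lower and none higher (median −1.27, percentile 0), 2 of them at 0 UMIs in KO saline. Cholesterol synthesis genes were higher in KO saline smooth muscle-like cells (median 0.69, percentile 100, 9 of 14 higher and none lower), with Dhcr7 at 1.15 and Insig1 at 1.11, as were immediate early and heat shock genes (median 0.59, 9 of 18 higher, 1 lower). Unfolded protein response genes were higher in smooth muscle-like cells (median 0.57, 6 of 13) with none lower, and in fibroblast-like cells (median 0.88, 8 of 15 higher, 1 lower; Sdf2l1 2.70 and Pdia6 1.83). MHC class II genes of phagocyte-like cells were higher in KO saline in 6 of 6 members (median 1.86; H2-Ab1 2.05 and H2-Eb1 1.98), and fibroblast-like cytokine genes had a median of 0.92 (5 of 6 higher).

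Between the saline libraries 139 genes were at least 2-fold higher and 117 lower in KO among 10645 in smooth muscle-like cells. In fibroblast-like cells 82 were higher and 116 lower among 4137 (65 and 144 under TMM scaling), and in phagocyte-like cells 23 and 32 among 1069 (19 and 41). Kank4 (5.28 against 0.654 CPM, log2 ratio 3.01, interval 2.497 to 3.58) and the circadian genes Nr1d1 (120 against 21.8 CPM, 2.46, interval 2.37 to 2.55) and Dbp (58.1 against 13.5 CPM, 2.11, interval 1.99 to 2.23) were higher in KO smooth muscle-like cells. Fkbp5 (3.50 against 53.3 CPM, −3.93, interval −4.13 to −3.74), Cyp2b10 (0.150 against 2.81 CPM, −4.23, interval −5.32 to −3.31) and the mitochondrial folate enzyme gene Mthfd2 (16.3 against 146 CPM, −3.16, interval −3.25 to −3.07) were lower.

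In saline fibroblast-like cells Nr1d1 (81.8 against 8.33 CPM, 3.30, interval 2.76 to 3.87) and Sdf2l1 (119 against 18.3 CPM, interval 2.32 to 3.09) were higher in KO. Angptl7 (147 against 1165.0 CPM, −2.98, interval −3.16 to −2.81), Mrgprg (6.06 against 73.3 CPM, −3.60, interval −4.56 to −2.77) and Tmem52 (3 UMIs against 104, −4.03, interval −6.33 to −2.44) were lower. Phagocyte-like cells of KO saline had more Tmsb10 (565 against 88.1 CPM, 2.68, interval 2.33 to 3.04, but 0.504 at Leiden resolution 2), Il1b (809 against 162 CPM, 2.32, interval 2.05 to 2.59) and H2-Ab1 (3204 against 771 CPM, interval 1.93 to 2.18, but 1.15 at Leiden resolution 2). Lyve1 (700 against 2131 CPM, −1.61, interval −1.80 to −1.42), Ms4a6c (386 against 1188 CPM, −1.62, interval −1.88 to −1.37) and Ifi27l2a (1995 against 5069 CPM, −1.35, interval −1.46 to −1.23) were lower. Fkbp5, Cyp2b10, Angptl7, Mrgprg and Lyve1 were lower than in WT saline both in KO saline and in WT AngII, so their genotype and AngII differences rest on the same WT saline library. KO saline held 356 fibroblast-like and 56 phagocyte-like cells. Giving mixed clusters to their first class turned the fibroblast split to 196 higher and 140 lower and brought the interferon-stimulated median to −1.10.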

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

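Thinning of cells was chosen before the data were examined, and the other tests described here were chosen after the patterns had been seen. Bounds were set before the tested value was computed, except in the tests of macrophage RNA and of free Hoxc10 and Hoxa10 RNA, which were written after expression values had been seen.

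Of the differences between the AngII ratios of the genotypes (KO ratio minus WT ratio), 5 list medians were singled out because the list median lay above 0 in WT and below 0 in KO and the median difference was at least 2-fold. None of these differences was tested, since each rests on 4 libraries. They were −2.393 for interferon-stimulated genes and −1.657 for MHC class I presentation in fibroblast-like cells, and −1.515 for cell cycle, −1.633 for MHC class I and −2.703 for MHC class II presentation in phagocyte-like cells. In phagocyte-like cells the KO saline side of each rests on 56 cells, and there MHC class II genes were higher than in WT saline.

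Small clusters outside every compared class were present above the level of the saline library of the same genotype. Cells led by Rab26os, Ptcra and Hist1h4h formed 0.2714% of WT AngII (23 cells, against 3 in WT saline) and 0.7063% of KO AngII (60 cells, against 3 in KO saline). An unnamed set led by Ccl21a, Cldn5 and Egfl7 was 0.2472% of KO AngII (21 cells, against 1), with 6 cells in WT AngII and 4 in WT saline. A part of cluster 2 led by Adamtsl1, Msx2 and Dlx5 was 1.109% of WT AngII (94 cells, against 10), with 54 cells in KO AngII and 166 in KO saline. Another unnamed part of cluster 2, with the same genes among its leading genes, held 232 cells of WT saline and 0 of WT AngII. Cluster 2 as a whole held 340 cells of WT saline, 161 of WT AngII, 291 of KO saline and 179 of KO AngII. The higher WT AngII share of the first part therefore rests on how cluster 2 was divided. An unnamed set led by Ube2c, Spc25 and Ccna2 was 0.118% of WT AngII (10 cells, against 0) and 0.8946% of KO AngII (76 cells, against 0). It is part of cluster 5, which is led by Ube2c and Cenpa, lies mostly inside the compared classes and held 175 cells of WT AngII, 428 of KO AngII, 6 of WT saline and 9 of KO saline.

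Interferon-stimulated genes were lower in fibroblast-like cells of KO AngII than of WT AngII by a median log2 ratio of −3.06. Thinning each cell to the same number of UMIs left the median at −3.278. The ratios are already shares of class totals, and random thinning keeps such shares about the same, so it could hardly move the median and cannot test depth. Removing the 10% of fibroblast-like cells with the largest interferon share (196 in KO AngII and 169 in WT AngII) left the median at −3.471. Those cells were picked by the same genes and cut from both libraries, so the cut can itself lower the ratio. It cannot decide whether a small set of interferon-high cells is the source. RNA of macrophages in fibroblast droplets would bring all abundant macrophage transcripts at about equal shares. The excess of the 23 interferon-stimulated genes in WT AngII fibroblast-like cells over KO AngII equals a median of 45.88% of their phagocyte CPM in WT AngII (11.18% to 166.5%), whereas 7 macrophage transcripts reached 0.1883% (C1qa) to 0.310% (Tyrobp) of theirs. The macrophage values argue against macrophage RNA as the whole source, while a small set of interferon-high cells was not decided. Fibroblast-like cells of KO AngII were the deeper ones, with a median of 11846 UMIs against 9051.5 in WT AngII. These values argue against lower depth in KO AngII as the source. A difference between the pooled mice, their handling or the library preparation stays open because each group is 1 library. The genotype itself also stays open and was not tested, since Tmem173 counts do not separate the genotypes. Several libraries per genotype from separate mice, with STING protein measured, would be needed to test it.

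Hoxc10 and Hoxa10 were high in smooth muscle-like cells of KO AngII, with 495 and 465 UMIs, against 15 and 25 in WT saline, 0 and 5 in WT AngII and 6 and 12 in KO saline. Free RNA would reach droplets of every class alike. Fibroblast-like and phagocyte-like cells held 97 and 5 UMIs of both genes, in 1955 and 485 cells. Pooled, their UMIs per cell were 23.8% of those per smooth muscle-like cell. The upper 95% limit was 28.89%, just above the limit set for excluding free RNA. Nearly all of these UMIs lay in fibroblast-like cells, and phagocyte-like cells had far fewer per cell. Free RNA alone would not differ so between classes. The pooled share therefore cannot say how much is free RNA, which stays open only as part of the source. Within the library, 4 other homeobox genes of caudal position had a median log2 ratio of 3.456 in the clusters led by Hoxc10 (1097 cells) over the other smooth muscle-like cells, and 6 genes of rostral position one of −1.069. Against this, Hoxb9 (−1.35) was lower and Hoxc4 (1.69) higher, and 3 of the caudal genes (Hoxc9, Hoxc8 and Hoxa9) are neighbours of Hoxc10 or Hoxa10 in the genome. A candidate explanation is that the dissected piece of this library reached farther down the aorta; a difference due to genotype or AngII in these cells stays open.

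Fkbp5 was lower, and Nr1d1 and Dbp higher, in smooth muscle-like cells of KO saline than of WT saline. For Fkbp5 it is WT saline that stood apart, with 53.3 CPM against 3.25 in WT AngII, 3.50 in KO saline and 4.69 in KO AngII. If tissue was taken at another time of day, other clock genes that follow Dbp should stand above those that oppose it, but the gap of their medians was 0.1877 in smooth muscle-like and 0.2783 in fibroblast-like cells, which decides neither way. Different glucocorticoid exposure would lower other responsive genes, and 7 of these had a median of −0.1924 in smooth muscle-like and −0.6746 in fibroblast-like cells. The first value lay past the bound of −0.25 set beforehand as evidence against that source, but members ranged from −2.364 for Pdk4 to 1.047 for Ddit4, wider than the margin, and the judgement that this leaves it open was made after the value was seen. Time of day and glucocorticoid exposure cannot be told apart from genotype here, because the members went both ways and the genotypes are single libraries.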

How the results depend on the processing

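Gene ratios, list medians and counts of genes were recomputed under 20 alternative settings, class shares under 13 and the Tmem173 level under 7, changing one choice at a time. Of the 20, 14 were chosen before the data were examined and 6 after seeing the data. Overlaps, correlations and percentiles were not recomputed. No paired analysis was possible because each group is 1 library. All 72 values of genes picked by the naming rule kept their sign in every setting and 71 stayed at least 2-fold apart in all of them, Tmsb10 in phagocytes of the saline libraries being the exception (0.5035 at Leiden resolution 2). Of their 1440 alternative values 124 moved outside the counting interval, 42 of them with thinned cells, and 27 of the 72 ratios came nearer to 0 by over 1.5-fold in at least 1 setting. These genes were picked for lying farthest from 0, so keeping their sign was largely set by that choice. Other UMI minimums and no free RNA filter change only which genes are eligible, so they could not move these ratios. Of the list medians that open a comparison, none turned its sign: 87 values moved outside the 95% counting interval of the main median (UMIs redrawn from Poisson distributions) and 272 did not, and of the median differences between genotypes 12 moved and 48 did not. Counts of genes with differences at least 2-fold moved in 7 of 60 values. The phagocyte interferon median between saline libraries could not be computed with a minimum of 300 UMIs. These 21 medians were picked after values and their sensitivity had been seen. Among all other list medians 843 values moved, 5 reversed and 4082 did neither, and among the other differences 192 moved, 4 reversed and 1046 did neither. A value was called reversed only if its sign turned and the main median was at least 1.5-fold from 0. Sign changes of smaller medians are counted as moved or as neither. Counts of genes at least 2-fold apart stayed within 1.5 times in 215 of 240 values and shares of the 3 compared classes stayed within their interval in 109 of 156. A minimum of 200 detected genes removed and added no cell, so it tests nothing, and clustering settings cannot alter Tmem173 over all cells. Keeping the called doublets adds 3 cells, so its effects show how far clustering alone moves a value. Comparisons with KO saline rest on 56 phagocyte-like and 356 fibroblast-like cells. Values that reversed belong to fibroblast endothelial activation in KO (main median −0.78), smooth muscle cell cycle between AngII libraries (0.73) and the fibroblast cell cycle difference (−1.80). These, and the values of opening medians, differences, shares, counts and Tmem173 that moved, follow by setting, with (WT) and (KO) for AngII against saline in that genotype, (AngII) and (saline) for KO against WT in those libraries, and class names without -like. Fewer or more eligible genes explain the counts at other UMI minimums; elsewhere the cause was not tested.

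With at least 1000 detected genes per cell the shares were smooth muscle 79.6% in WT saline, 60.6% in WT AngII and 83.3% in KO saline and fibroblast 10.3% in WT saline and 2.499% in KO saline. Medians were smooth muscle contractile −0.34 (KO), fibroblast interferon −2.26 (KO) and phagocyte MHC II −1.65 (KO). With at most 10% mitochondrial UMIs the shares were smooth muscle 77.7% in WT saline. The medians were smooth muscle unfolded protein 1.02 (WT), smooth muscle contractile −0.33 (KO) and phagocyte MHC II −1.74 (KO). Median differences between genotypes were −2.83 for MHC II in phagocyte. With the called doublets kept the shares were fibroblast 12.3% in WT saline and smooth muscle 85.2% in KO saline and 65.7% in KO AngII. List medians were smooth muscle contractile −0.33 (KO) and phagocyte MHC II −1.73 (KO). Genotype differences had medians of −2.82 for MHC II in phagocyte. At Leiden resolution 0.5 the medians were smooth muscle contractile −0.28 (KO), fibroblast fibrosis 2.59 (WT) and phagocyte MHC II −1.73 (KO). At Leiden resolution 2 the shares were smooth muscle 65.3% in WT AngII. Medians were smooth muscle contractile −0.33 (KO) and fibroblast fibrosis 2.49 (WT). Between genotypes the median differences were 0.0510 for cell cycle in fibroblast and −2.40 for MHC II in phagocyte. With each library clustered on its own the shares were smooth muscle 80.5% in KO saline and 62.6% in KO AngII. The medians were smooth muscle contractile −0.28 (KO), smooth muscle fibrosis 1.502 (KO), smooth muscle cell cycle −0.33 (AngII), fibroblast fibrosis 2.77 (WT) and 2.76 (KO) and phagocyte MHC II −1.48 (KO). Median differences between genotypes were 0.16 for cell cycle in fibroblast.

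Of the alternatives added after seeing the data, those on doublets, naming and cells moved the following. After removal of the cells with the highest doublet scores the shares were smooth muscle 82.4% in WT saline, 69.7% in WT AngII, 85.5% in KO saline and 67.7% in KO AngII and fibroblast 12.5% in WT saline, 21.0% in WT AngII and 24.0% in KO AngII. List medians were smooth muscle unfolded protein 1.003 (WT), smooth muscle contractile −0.32 (KO), fibroblast fibrosis 2.48 (WT) and phagocyte MHC II −1.70 (KO). Genotype differences had medians of 0.15 for cell cycle in fibroblast. Without dividing clusters the shares were fibroblast 14.1% in WT saline, 21.2% in WT AngII and 7.38% in KO saline, phagocyte 3.16% in WT saline, 8.87% in WT AngII, 0.699% in KO saline and 7.08% in KO AngII and smooth muscle 65.4% in WT AngII, 88.9% in KO saline and 61.3% in KO AngII. Medians were smooth muscle contractile −0.28 (KO), fibroblast fibrosis 2.49 (WT) and 2.73 (KO), fibroblast interferon −1.47 (KO) and −1.13 (saline), fibroblast endothelial activation 1.43 (KO), phagocyte resident macrophage −1.68 (WT) and phagocyte recruited monocyte 2.25 (WT). Between genotypes the median differences were −2.04 for interferon in fibroblast and 0.33 for cell cycle in fibroblast. With leading genes judged over all other cells the shares were smooth muscle 61.9% in WT saline, 60.8% in WT AngII, 68.0% in KO saline and 55.8% in KO AngII. The medians were smooth muscle fibrosis 1.81 (WT) and 1.64 (KO). With mixed clusters given to their first class the shares were smooth muscle 80.8% in WT saline and 90.4% in KO saline, fibroblast 22.2% in WT AngII, 6.76% in KO saline and 25.5% in KO AngII and phagocyte 8.57% in WT AngII, 0.690% in KO saline and 6.82% in KO AngII. List medians were smooth muscle fibrosis 1.79 (WT), smooth muscle contractile −0.29 (KO), fibroblast interferon −1.59 (KO) and −1.10 (saline), fibroblast endothelial activation 1.46 (KO) and phagocyte recruited monocyte 2.33 (WT). Genes at least 2-fold apart numbered fibroblast 336 (saline). Median differences between genotypes were −1.96 for interferon in fibroblast. Without the clusters led by Pam and Abhd2 the shares were smooth muscle 85.1% in KO saline, fibroblast 4.27% in KO saline and phagocyte 0.672% in KO saline. Medians were smooth muscle contractile −0.32 (KO) and smooth muscle fibrosis 1.47 (KO). Without the clusters led by Hoxc10 the Tmem173 level of KO AngII was 6.66 CPM. Shares were smooth muscle 59.0% in KO AngII, fibroblast 26.4% in KO AngII and phagocyte 6.56% in KO AngII. The medians were smooth muscle contractile −0.42 (KO) and smooth muscle fibrosis 1.58 (KO).

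With TMM factors the medians were smooth muscle contractile −0.39 (WT) and −0.13 (KO), smooth muscle fibrosis 1.89 (WT) and 1.70 (KO), smooth muscle unfolded protein 1.18 (WT), smooth muscle cholesterol 1.05 (AngII), fibroblast fibrosis 2.87 (WT) and 2.91 (KO), phagocyte resident macrophage −1.53 (WT) and phagocyte MHC II −1.40 (KO). Genotype differences had medians of −0.50 for unfolded protein in smooth muscle. With median-of-ratios size factors the medians were smooth muscle contractile −0.38 (WT) and −0.12 (KO), smooth muscle fibrosis 1.89 (WT) and 1.72 (KO), smooth muscle unfolded protein 1.18 (WT), smooth muscle cholesterol 1.06 (AngII), fibroblast fibrosis 2.87 (WT) and 2.89 (KO) and phagocyte MHC II −1.43 (KO). Between genotypes the median differences were −0.49 for unfolded protein in smooth muscle. With the mean of CPM per cell the medians were smooth muscle contractile −0.44 (WT) and −0.17 (KO), smooth muscle fibrosis 1.84 (WT) and 1.36 (KO), smooth muscle cholesterol 0.82 (AngII), fibroblast fibrosis 2.504 (WT) and 2.503 (KO), fibroblast interferon −1.58 (KO) and −0.91 (saline), phagocyte resident macrophage −1.51 (WT) and phagocyte recruited monocyte 3.39 (WT). Median differences between genotypes were −0.66 for unfolded protein in smooth muscle. With each cell thinned to 3000 UMIs the medians were smooth muscle contractile −0.47 (WT) and −0.19 (KO), smooth muscle fibrosis 1.85 (WT) and 1.44 (KO), smooth muscle cholesterol 0.77 (AngII), fibroblast fibrosis 2.80 (WT) and 2.77 (KO), fibroblast interferon −3.28 (AngII), phagocyte resident macrophage −1.47 (WT) and phagocyte MHC II −1.30 (KO). Genes at least 2-fold apart numbered phagocyte 449 (KO). Genotype differences had medians of −0.69 for unfolded protein in smooth muscle and −2.38 for MHC II in phagocyte. Genes with differences at least 2-fold numbered 275 in phagocyte.

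With a minimum of 10 UMIs the medians were fibroblast endothelial activation 0.0112 (KO) and phagocyte recruited monocyte 2.62 (WT). Genes at least 2-fold apart numbered smooth muscle 1712 (WT), 1780 (KO), 544 (AngII) and 714 (saline), fibroblast 2238 (WT), 2817 (KO), 1381 (AngII) and 999 (saline) and phagocyte 1513 (WT), 1299 (KO), 700 (AngII) and 969 (saline). Genes with differences at least 2-fold numbered 1002 in smooth muscle, 1696 in fibroblast and 1511 in phagocyte. With a minimum of 300 UMIs the medians were fibroblast interferon −1.14 (KO) and −0.97 (saline) and phagocyte recruited monocyte 3.46 (WT). Genes at least 2-fold apart numbered smooth muscle 578 (KO), 84 (AngII) and 161 (saline), fibroblast 565 (WT), 647 (KO), 305 (AngII) and 86 (saline) and phagocyte 192 (WT), 97 (KO), 56 (AngII) and 21 (saline). Between genotypes the median differences were −2.91 for interferon in fibroblast. Genes with differences at least 2-fold numbered 232 in smooth muscle, 207 in fibroblast and 61 in phagocyte. Without the free RNA filter the medians were smooth muscle fibrosis 1.85 (WT) and 1.77 (KO), smooth muscle unfolded protein 1.01 (WT) and fibroblast endothelial activation 0.75 (KO). Median differences between genotypes were −0.51 for unfolded protein in smooth muscle.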

Other observations

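Gene lists that opened no comparison showed further differences. Cell cycle genes were higher with AngII in smooth muscle-like cells of WT (median log2 ratio 1.95, 9 of 11 members higher) and KO (3.41, 12 of 16). They were also higher in fibroblast-like cells of WT (4.38, 13 of 16) and KO (2.17, 14 of 16). No member was at least 1.5-fold lower in these comparisons. The smooth muscle medians rest on different members, and over the same 11 genes the median KO ratio minus WT ratio was 0.52. The unnamed set led by Ube2c, Spc25 and Ccna2 (76 cells of KO AngII, 10 of WT AngII) lay outside the class. The smooth muscle cell cycle median of KO AngII over WT AngII (0.73) turned its sign in 1 alternative setting. In fibroblast-like cells the KO ratio minus the WT ratio had a median of −1.80, which turned its sign in 4 alternative settings. In phagocyte-like cells they were higher in WT (1.33, 15 of 16) but not in KO (−0.17, 2 higher and 2 lower of 16). Glycolysis and hypoxia genes were higher with AngII in fibroblast-like cells (0.80 in WT, 7 of 12 higher and 2 lower; 0.88 in KO, 7 higher and 1 lower) and in phagocyte-like cells (0.91 in WT, 9 of 12 higher and 1 lower; 0.74 in KO, 8 higher and none lower). Lipid handling genes were higher in KO phagocyte-like cells with AngII (1.02, 6 of 11 higher and 3 lower) and lower in KO fibroblast-like cells with AngII (−1.66, 6 of 8 lower and 2 higher).

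Immediate early and heat shock genes, which tissue dissociation is known to induce, were higher in smooth muscle-like cells of KO AngII than of WT AngII (median 0.75, 11 of 18 higher and none lower), with Dnajb1 at 1.30, Hspa1b at 1.28 and Hspa1a at 1.25, and of KO saline than of WT saline (0.59, 9 of 18 higher and 1 lower). They were lower with AngII in fibroblast-like cells (−0.53 in WT and −0.79 in KO) and in KO phagocyte-like cells (−0.99, 12 of 18 lower). Oxidative phosphorylation genes lay close to 0 in all 12 comparisons of class and libraries, with medians from −0.17 to 0.28. Components of the cGAS-STING pathway had medians from −0.45 to 0.16, and in fibroblast-like cells of KO AngII against WT AngII 3 of 8 members were lower and none higher (−0.34); Zbp1 and Ifi204 in this list are also interferon-stimulated genes.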
